A study of Homo sapiens with 4 samples.

How the data were processed

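RNA-seq libraries of U2OS cells were compared between 2 groups, sh-NC with DMSO (n = 2) and sh-PURB with doxycycline at 5 µg/ml (n = 2), both at 72 h. Per the labels' protocols, total RNA was extracted with TRIzol, ribosomal RNA was removed and libraries were made with Illumina TruSeq chemistry. The deposited values are TPM per gene symbol, from 1 table for each library. The submitters' processing notes name bcl2fastq 2.19, kallisto 0.44.0, sleuth and DESeq2, and the builds GRCh38 and GRCm38, with no role for any of them. The samples are labelled human, and how the mouse build was used is not given in the sources used here. Neither is the strand setting, the annotation release, or how transcripts were summed to genes. kallisto assigns reads to transcripts by compatibility, so reads shared by near-identical copies (U1 genes, histones, short RNA families) can be split between them, and such genes are uncertain one by one.

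TPM divides by transcript length and by the library's sum, so it keeps no depth, and no read count or counting interval can be given. The columns sum to 977570 to 981061, so they differ little between libraries, and their sum falls short of the full TPM scale: some rows of the original estimate are not analysed here. A row with a blank name held 0.921% to 1.66% of each library and was left out. Because TPM is a share, a change in abundant RNAs moves all other genes, and RNAs shorter than the fragments can be estimated poorly.

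Samples were grouped by their titles. The files hold 39519 genes. Genes with a TPM of at least 1 in at least 2 libraries were kept (14269). Values were taken as log2(TPM + 1) and compared in limma 3.58.1 under R 4.3.3, with empirical Bayes moderation and an intensity trend, and Benjamini-Hochberg adjustment over all tested genes at a threshold of 0.05. Differences on this scale understate the change of low genes. Ratios are of mean TPM. The fit had 2 residual and 2.92 prior degrees of freedom. Gene lists with at least 5 tested members were tested with limma camera at a preset inter-gene correlation of 0.01, adjusted over 32 lists, with camera at an estimated correlation and fry beside it. Camera compares a list with all other genes, and fry compares it with no change. At an estimated correlation, camera uses only the 2 residual degrees of freedom, as does fry's directional test, so a list can hardly pass either. Counts adjusted over the list alone use the same limma p-values. The target gene also had an exact two-sided permutation test. The unit in the files was the TPM that the chosen tests assumed.

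Named genes followed a rule fixed before the data were examined. PURB, PURA, HOTAIR, CDKN1A and MDM2 were named whatever their values. Then came, among genes at an adjusted p under 0.05 whose groups did not overlap, the 12 with the largest rise and the 12 with the largest fall in log2(TPM + 1), filled where fewer passed with genes of the smallest unadjusted p. Last came up to 4 members with the smallest unadjusted p from each list described. Pseudogenes and unnamed clones were counted but not named. Some genes that the rule names are not reported here, though they stay in all counts of calls. Gene names outside this rule are said to be chosen after their values were seen.

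Coordinates, gene types, transcript lengths and GC content came from GENCODE v29 on GRCh38. Of the gene symbols, 39140 matched by current names, 302 by older ones and 77 by neither. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

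The steps were tested on 20 simulated data sets of the sh-PURB against sh-NC comparison, with 14269 genes of which 200 were changed. The fit called 31.4% of genes changed 2-fold and 90.0% of genes changed 4-fold, with 4.19% false calls. A list shifted by 0.7 on the log2 scale was called in all 20, and 0 of the other 31 lists was. The simulated genes varied independently within lists. In the measured data some genes with changes above 4-fold were not called. Examples are TGFA (6.08-fold lower, limma adjusted p = 0.0615) and PHLDA1 (4.35-fold lower, limma adjusted p = 0.0716). The simulated shares may therefore not hold for the measured genes.

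Alternatives fixed beforehand were pseudocounts of 0.1 and 0.5, no filter, a filter at TPM 5, median-ratio rescaling, quantile normalization, TPM recomputed without genes above 1 percent of a library and without mitochondrial genes, the replicate number as a block, limma without trend, limma with robust moderation, and leaving out each library. Alternatives added after seeing the data were protein-coding genes only (rescaled to a common sum), removal of a trend with length and GC content per library (a spline with 4 degrees of freedom), rows of identical values counted once, and the p53 list without members of the ATF4 list.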

Results

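Total RNA depleted of ribosomal RNA was sequenced from U2OS cells, an established human osteosarcoma line. PURB encodes a single-stranded nucleic acid binding protein of the PUR family, and its knockdown by a short hairpin RNA (sh-PURB) was switched on with doxycycline at 5 µg/ml for 72 h. Control cells (sh-NC) received DMSO. There were 2 sh-NC and 2 sh-PURB libraries. The values were TPM, a length-scaled share of all transcripts, per gene symbol, and TPM keeps no read depth, so the depth behind each value is unknown. Between 22822 and 24156 genes were above 0 in a library, and 13298 to 14207 reached 1 TPM. The structured RNAs RN7SL1, RN7SL2, RN7SK, RMRP and RPPH1 took 59.4% to 65.2% of the total, and protein-coding genes 25.3% to 26.9%. The labels do not say that the libraries came from separate cultures. The limma p-values of single genes therefore measure only the spread between these libraries, which may be technical. For gene lists, camera with the preset correlation measures spread across genes instead, so its small p-values do not stand for repeated cultures. All sh-PURB libraries and no sh-NC library had doxycycline, so each difference is one between knockdown with doxycycline and control with DMSO. The labels do not say whether both sh-PURB libraries used the same hairpin.

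PURB mRNA, the target of the hairpin, was measured first in every library. It stood at 5.29 and 6.55 TPM in the sh-NC libraries and at 2.46 and 2.69 TPM in the sh-PURB libraries, which is 43.5% of the control mean (5.92 ± 0.896 against 2.58 ± 0.160 TPM, mean ± SD, n = 2 each). The difference on the log2(TPM + 1) scale was -0.95 with a standard error of 0.17. Its limma adjusted p over all tested genes was 0.102, above the threshold, and 0.0314 when protein-coding genes alone were fitted, an alternative chosen after seeing the data. That fit gave a difference of -1.07 with a standard error of 0.199, no larger beside its error than over all genes. An exact two-sided permutation test gave p = 0.333, the smallest that 2 libraries against 2 allow. PURB lies on chromosome 7 at 44876293 to 44885361, minus strand (GRCh38, GENCODE annotation). Its paralog PURA was at 1.16 ± 0.418 TPM in sh-NC and 1.85 ± 0.260 TPM in sh-PURB (limma adjusted p = 0.485).

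The series title joins PURB to the long noncoding RNA HOTAIR and to promoter-specific activation by p53, so HOTAIR and p53 targets were looked at next. HOTAIR, transcribed antisense within the HOXC cluster (chromosome 12, 53962308 to 53974956, minus strand), was at 2.93 ± 1.21 TPM in sh-NC and 1.40 ± 0.451 TPM in sh-PURB, 47.8% of control. The libraries did not overlap, and the limma adjusted p was 0.363. Strand-specific counting was not stated in the sources used here, so reads of HOTAIR and of genes on the opposite strand cannot be separated. CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21 (chromosome 6, 36676460 to 36687339), was at 42.5 ± 8.48 TPM in sh-NC and 70.9 ± 4.15 TPM in sh-PURB, a ratio of 1.67. It missed the threshold over all genes (limma adjusted p = 0.143) and passed it when protein-coding genes alone were rescaled and refitted (0.0302). The refit changed the test as well as the number of genes, as the unadjusted limma p went from 0.00630 to 0.000702. MDM2, the ubiquitin ligase that restrains p53 (chromosome 12, 68808176 to 68850686), was at 41.3 ± 6.24 and 45.0 ± 1.55 TPM (limma adjusted p = 0.725).

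**Figure D1:**
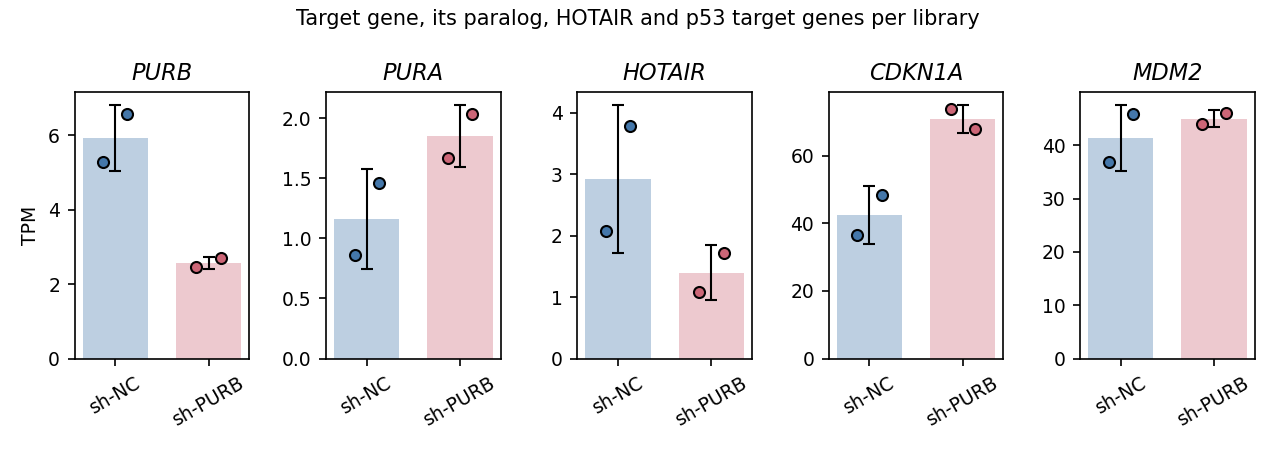
TPM of PURB, PURA, HOTAIR, CDKN1A and MDM2 in the 2 sh-NC libraries (blue) and the 2 sh-PURB libraries (red). Bars are group means, error bars are SD and points are libraries. The PURB libraries of the knockdown lie at 2.46 and 2.69 TPM, under both controls, and the CDKN1A libraries of the knockdown lie above both controls.

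Among 14269 tested genes, limma called 41 at an adjusted p under 0.05, 12 higher and 29 lower in sh-PURB. They were 21 protein-coding genes (4 higher, 17 lower), 19 genes of short RNAs (7 higher, 12 lower) and 1 long noncoding RNA. Of the short RNA genes, 8 were copies of U1 small nuclear RNA with identical values. At an unadjusted p under 0.05 there were 2184 genes (824 higher, 1360 lower) where chance gives 713. Both sh-PURB libraries lay above both sh-NC libraries for 2648 genes and below them for 4185, together 47.9% of genes where chance gives 33.3%. A pseudocount of 0.1, no filter on level or a limma fit without the trend left 0 genes past the limma threshold. So did leaving out any library, but that fit has 1 residual degree of freedom, so its count does not show how far the calls depend on a library. All 41 genes kept their direction in each of these fits. Protein-coding genes alone, rescaled to a common sum, gave 407 calls (157 higher, 250 lower), among them all 21 protein-coding genes called over all genes. That fit can give a smaller p at a like ratio of difference to standard error, so part of the gain lies in the test. With TPM recomputed after leaving out the most abundant and the mitochondrial genes, the median difference of all genes moved from -0.06 to 0.08 and the calls were 26 higher and 34 lower, 43.3% higher in place of 29.3%. Median-ratio rescaling gave 30 higher and 50 lower.

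Among the genes that rose most, ANO2, ANXA3 and ASNS had signal in both groups. ANO2, a calcium-activated chloride channel, went from 0.444 ± 0.162 to 5.74 ± 0.358 TPM, and the annexin ANXA3 went from 1.33 ± 0.0611 to 8.23 ± 1.35 TPM. ASNS, asparagine synthetase, rose 3.18-fold (20.3 ± 1.53 to 64.6 ± 7.79 TPM), and the noncoding RNA LINC01029 rose 2.18-fold. Their limma adjusted p-values lay between 0.0464 and 0.0488. SUN3 had a ratio of 3.37 and just missed the threshold. The other 6 named genes with a rise were short RNA genes, SNORD116-29, MIR548AD, MIR1285-1, MIR3175, MIR191 and SNORD116-14, each listed at 0 in both sh-NC libraries and above 0 in both sh-PURB libraries (MIR548AD at a mean of 10.6 TPM and MIR191 at 5.49 TPM). A listed 0 can be a failed estimate for so short a transcript, so no fold is given.

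IGFBP5, a secreted binding protein of insulin-like growth factors, went from 70.3 ± 1.37 to 8.09 ± 3.10 TPM, which is 8.69-fold lower. The pseudokinase TRIB2 was 6.49-fold lower, the integrin subunit ITGA2 5.36-fold, the matrix protein TGFBI 5.24-fold, SPP1 (osteopontin) 5.21-fold, the collagen chain COL6A3 5.11-fold and SYTL5, a synaptotagmin-like protein, 5.74-fold lower. SERPINA1, which encodes alpha-1 antitrypsin, was 4.31-fold lower, and the inositol transporter SLC5A3 fell from 65.8 ± 3.53 to 17.1 ± 1.17 TPM. The small nucleolar RNA SNORA18 fell 4.06-fold, and MIR378J and MIR7974 were listed at 0 in both sh-PURB libraries. TIMP1, an inhibitor of metalloproteinases, had the smallest p-value, falling from 757 ± 2.63 to 235 ± 4.46 TPM with a log2 difference of -1.68 (SE 0.077, limma adjusted p = 0.0374). The adjusted p-values of these genes in limma lay between 0.0374 and 0.0464. With rows of identical values counted once, ANO2, ANXA3, LINC01029, MIR3175, ITGA2, SAT1 and the U1 gene RNU1-1 moved to an adjusted p of 0.054, above the threshold. A filter at TPM 5 did the same to ANO2, MIR1285-1 and MIR378J, and removal of a length and GC trend to SNORD116-14, LINC01029 and SAT1.

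**Figure D2:**
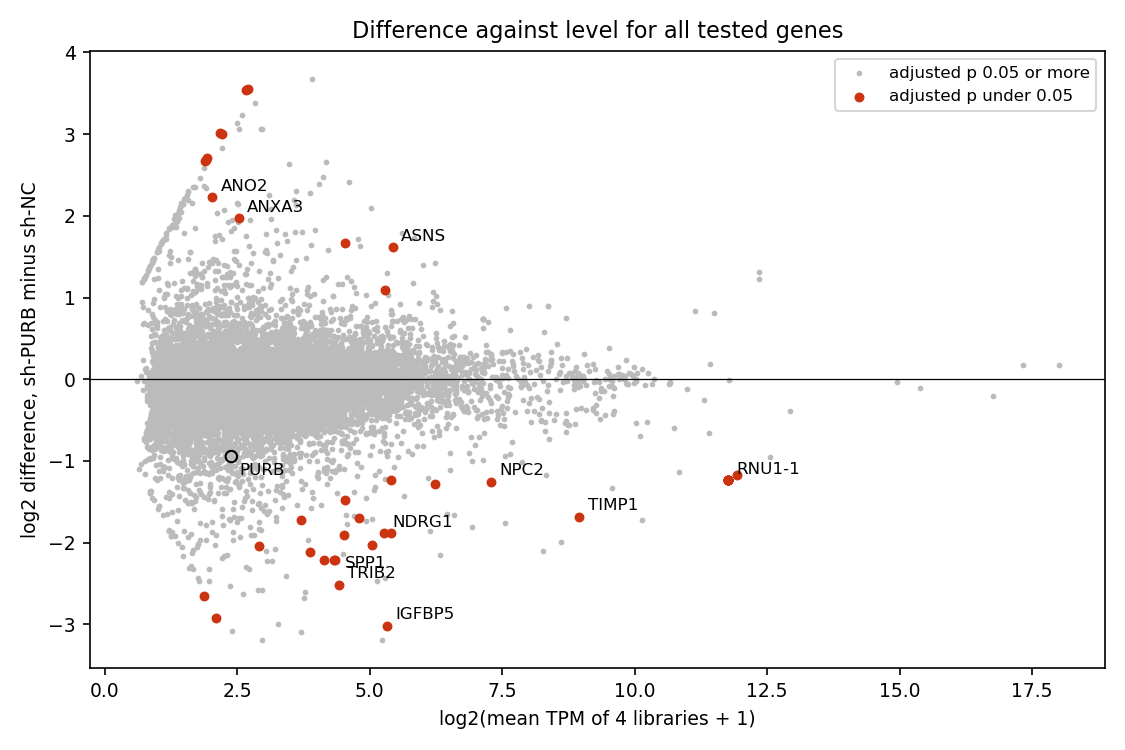
Difference between sh-PURB and sh-NC, as log2(TPM + 1), against the level of each of the 14269 tested genes, as log2 of the mean TPM of the 4 libraries plus 1. Red points are the 41 genes at a limma adjusted p under 0.05 and the open circle is PURB. TIMP1 and the U1 gene RNU1-1 are called lower at high levels, and most other calls have larger differences at lower levels.

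Gene lists fixed before the data were examined were then compared with all other genes by limma camera. Of 32 lists with at least 5 tested members, 16 passed an adjusted p of 0.05, 10 higher and 6 lower. None passed with an inter-gene correlation estimated from these libraries or in fry's directional test. Camera at an estimated correlation has only 2 residual degrees of freedom, so a list could hardly pass it. Those estimates ran from -0.14 to 0.94, against the preset 0.01. With the preset value, camera sets a list against the spread across genes, taken as nearly independent, and not the spread between libraries. Fry's directional test asks another question, whether a list differs from no change and not from other genes. It too rests on the 2 residual degrees of freedom, so a list could hardly pass it. Even the ATF4 list had a fry adjusted p of 0.118. In fry's mixed test for change in either direction 20 lists passed. Apart from the list of all p53 targets, 15 passed, and 9 did without sh-PURB replicate 2.

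Genes of the integrated stress response, which the transcription factor ATF4 drives, were higher. Of 36 tested members 33 lay above 0 with a median log2 difference of 0.72, and in 31 both sh-PURB libraries exceeded both controls, where chance gives 16.7%. ASNS alone was called over all genes, and 28 members were called higher and 1 lower (DDIT4, named after seeing its value) when adjusted over the list alone. PCK2, mitochondrial phosphoenolpyruvate carboxykinase, was at 2.34 times control, PSAT1 of serine synthesis at 2.81 times and the secreted hormone FGF21 at 6.49 times. The camera adjusted p was 5.77e-21, with an adjusted p = 0.559 under an estimated correlation. Among protein-coding genes alone, 20 members were called higher and 0 lower.

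The p53 targets moved in both directions. The list of 81 tested targets was placed higher by camera (adjusted p = 0.00201, adjusted p = 0.559 with an estimated correlation), but its median log2 difference was 0.09, with 52 members above 0 and 29 below. Against no change, fry gave this list an adjusted p of 0.474, in a test that could hardly be passed here. Over the other settings this median ran from 0.05 without sh-NC replicate 1 to 0.24 with recomputed TPM. Over all genes, 0 were called higher and 1 lower by limma, against 12 higher and 4 lower at an unadjusted p under 0.05. Among protein-coding genes alone, 3 members were called higher (NEFL, GADD45A and CDKN1A) and 2 lower (SAT1 and TGFA). The gene called over all genes was SAT1, a polyamine acetyltransferase, which fell from 19.0 ± 2.28 to 5.05 ± 0.579 TPM. Adjusted over the list alone, the neurofilament gene NEFL was higher (2.16 times control) and SAT1 and the growth factor TGFA were lower (TGFA at 0.165 of control). NEFL is also in the list of neural markers, whose other members went both ways. TUBB3 was at 13.3 and 12.3 TPM in sh-NC and 19.3 and 21.2 TPM in sh-PURB, SOX2 at 2.90 and 3.46 against 0.917 and 2.23 TPM, and NEFM and INA were listed at 0 in every library. In the sub-list for cell cycle arrest, 5 of 17 members were higher when adjusted over the list alone: CDKN1A, GADD45A at 1.78 times control, CCNG1 at 1.39, RPS27L at 1.35 and SESN2 at 1.81. BTG1 was lower, a gene named after seeing its value. Camera gave this sub-list an adjusted p of 0.0210 (adjusted p = 0.559 with an estimated correlation), which became 0.0654 without sh-NC replicate 1 and 0.0668 without sh-PURB replicate 2.

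The other p53 sub-lists differed in their members. The feedback and ubiquitin ligase list (8 tested) was higher with a median of 0.19 and an adjusted p of 0.0129 by camera (adjusted p = 0.559 with an estimated correlation, 0.0568 without sh-PURB replicate 2). Its median was 0.31 without sh-NC replicate 2 and 0.36 with recomputed TPM. CCNG1 and FBXO22 were the 2 members higher when adjusted over the list alone. The metabolism, ferroptosis and autophagy list (16 tested) had a camera adjusted p of 0.0135 (adjusted p = 0.559 with an estimated correlation) and 1 member called, SAT1, which was lower. SLC7A11, the cystine transporter, stood at 2.05 times control. Like SESN2 and GDF15 of this list, it is also in the ATF4 list, and this list was not retested without them. Among protein-coding genes alone 1 member was called higher, SLC7A11 (limma adjusted p = 0.04999), and 1 lower. The apoptosis list (17 tested) did not pass (camera adjusted p = 0.121), with a mean of -0.01 and a median of 0.06, which ran from 0.03 with no filter to 0.26 with the filter at TPM 5. Within it PHLDA1 was at 0.230 of control and lower when adjusted over the list alone, while BCL2L1, BAX and FAS were at 1.58, 1.25 and 1.39 times control without passing. The DNA repair list (10 tested) did not pass (adjusted p = 0.769 by camera, mean -0.01, median 0.02, or -0.23 without sh-PURB replicate 2 and 0.18 without sh-PURB replicate 1), and neither did the p53-linked long noncoding RNAs (11 tested, adjusted p = 0.102). The latter passed without sh-PURB replicate 1 (0.00289).

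Cell cycle and histone genes were lower. All 19 tested replication-dependent histone genes lay lower in both sh-PURB libraries than in both controls, with a median of -0.44, and 18 were called lower when adjusted over the list alone. H1-1 was at 0.570 of control and H3C1 at 0.693. The median of this list was -0.29 with recomputed TPM. None was called over all genes by limma, against 18 at an unadjusted p under 0.05 and 6 called lower of 18 among protein-coding genes alone (camera adjusted p = 5.98e-11, adjusted p = 0.559 with an estimated correlation). Of 42 G2/M and mitosis genes, 39 lay below 0 with a median of -0.28 (-0.15 with recomputed TPM), and NUSAP1 (0.573 of control), TOP2A (0.640) and KIF20A (0.622) were lower when adjusted over the list alone (adjusted p = 1.22e-07 by camera, adjusted p = 0.559 with an estimated correlation). The 40 G1/S and DNA replication genes had a median of -0.17 (from -0.03 with recomputed TPM to -0.26 without sh-NC replicate 1), with MCM4 at 0.782 of control and PCNA at 0.755, and no member called by limma (5 lower and 0 higher at an unadjusted p under 0.05). Their camera adjusted p of 0.0164 (adjusted p = 0.691 with an estimated correlation) was lost without sh-NC replicate 2 (0.143), without sh-PURB replicate 2 (0.498), after median-ratio rescaling (0.083), with recomputed TPM (0.155) and among protein-coding genes (0.0525).

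Genes of hypoxia and glycolysis and genes of the extracellular matrix were lower. Of 31 hypoxia and glycolysis genes 29 lay below 0 (median -0.50), 1 was called over all genes and 17 were lower when adjusted over the list alone. Among protein-coding genes alone 11 were called lower. The gene called over all genes was NDRG1, which fell from 59.8 ± 1.01 to 15.5 ± 0.553 TPM. The aldolase ALDOC was at 0.319 of control and the kinase PFKFB4 at 0.351, and carbonic anhydrase CA9 went from 3.46 ± 0.625 TPM to values of 0 and 0.151 TPM (camera adjusted p = 8.62e-11, adjusted p = 0.559 with an estimated correlation). Of 30 matrix genes 26 lay below 0 (median -0.63, but -0.26 without sh-PURB replicate 1). TIMP1, COL6A3 and TGFBI were called over all genes, and 10 members were lower and 1 higher when adjusted over the list alone (camera adjusted p = 4.24e-06, adjusted p = 0.559 with an estimated correlation). Fibronectin, FN1, was at 0.171 of control (65.2 ± 20.5 to 11.1 ± 2.34 TPM). The 1 higher member was the collagen COL12A1, named after seeing its value. Among protein-coding genes alone, 9 members were called lower and 1 higher.

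Cholesterol synthesis genes were higher as a list. Of 23 members 20 lay above 0 (median 0.41, 0.27 without sh-PURB replicate 1, camera adjusted p = 1.22e-07, adjusted p = 0.559 with an estimated correlation). Over all genes 0 members were called higher and 1 lower by limma, and among protein-coding genes alone 2 higher and 1 lower. Adjusted over the list alone, 4 members were higher and 1 was lower. The higher members were FDFT1 (2.70 times control), INSIG1 (3.15), LSS (1.51) and FDPS, the last named after seeing its value.

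Respiratory chain genes were slightly higher. The 61 nuclear-encoded genes of oxidative phosphorylation had a median of 0.16 with 53 above 0 (0.09 without sh-PURB replicate 1, 0.31 with recomputed TPM, camera adjusted p = 4.61e-08, adjusted p = 0.559 with an estimated correlation), and CYC1 was at 1.21 and UQCRFS1 at 1.35 times control. No member was called by limma (8 higher at an unadjusted p under 0.05). The 13 mitochondrially encoded mRNAs had a median of 0.31, which was 0.06 without sh-NC replicate 1, 0.66 without sh-NC replicate 2 and 0.19 without sh-PURB replicate 2, with MT-ATP6 at 1.76 times control (137 ± 57.0 to 241 ± 33.3 TPM). Their camera adjusted p of 0.000671 (adjusted p = 0.597 with an estimated correlation) became 0.141 without sh-NC replicate 1. The 79 cytosolic ribosomal protein genes passed camera (adjusted p = 0.0129, adjusted p = 0.715 with an estimated correlation) and RPLP1 was at 1.20 times control. Their median was 0.02, and scaling moved it, to 0.10 after median-ratio rescaling (camera adjusted p = 8.42e-06), 0.14 after quantile normalization (1.05e-12), 0.17 with recomputed TPM (8.82e-10) and 0.07 among protein-coding genes (4.03e-05). The call was lost without sh-NC replicate 1 (median 0.0049, 0.0806) and without sh-PURB replicate 2, where the median turned to -0.009 (0.0922), and the median was 0.05 without either of the other libraries. The 20 host genes of small nucleolar RNAs had a median of 0.13 (0.04 without sh-NC replicate 1, 0.21 after median-ratio rescaling, 0.28 with recomputed TPM) and SNHG16 was at 1.20 times control (camera adjusted p = 0.0187, adjusted p = 0.559 with an estimated correlation, 0.104 without sh-NC replicate 1 and 0.054 without sh-PURB replicate 2).

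**Figure D3:**
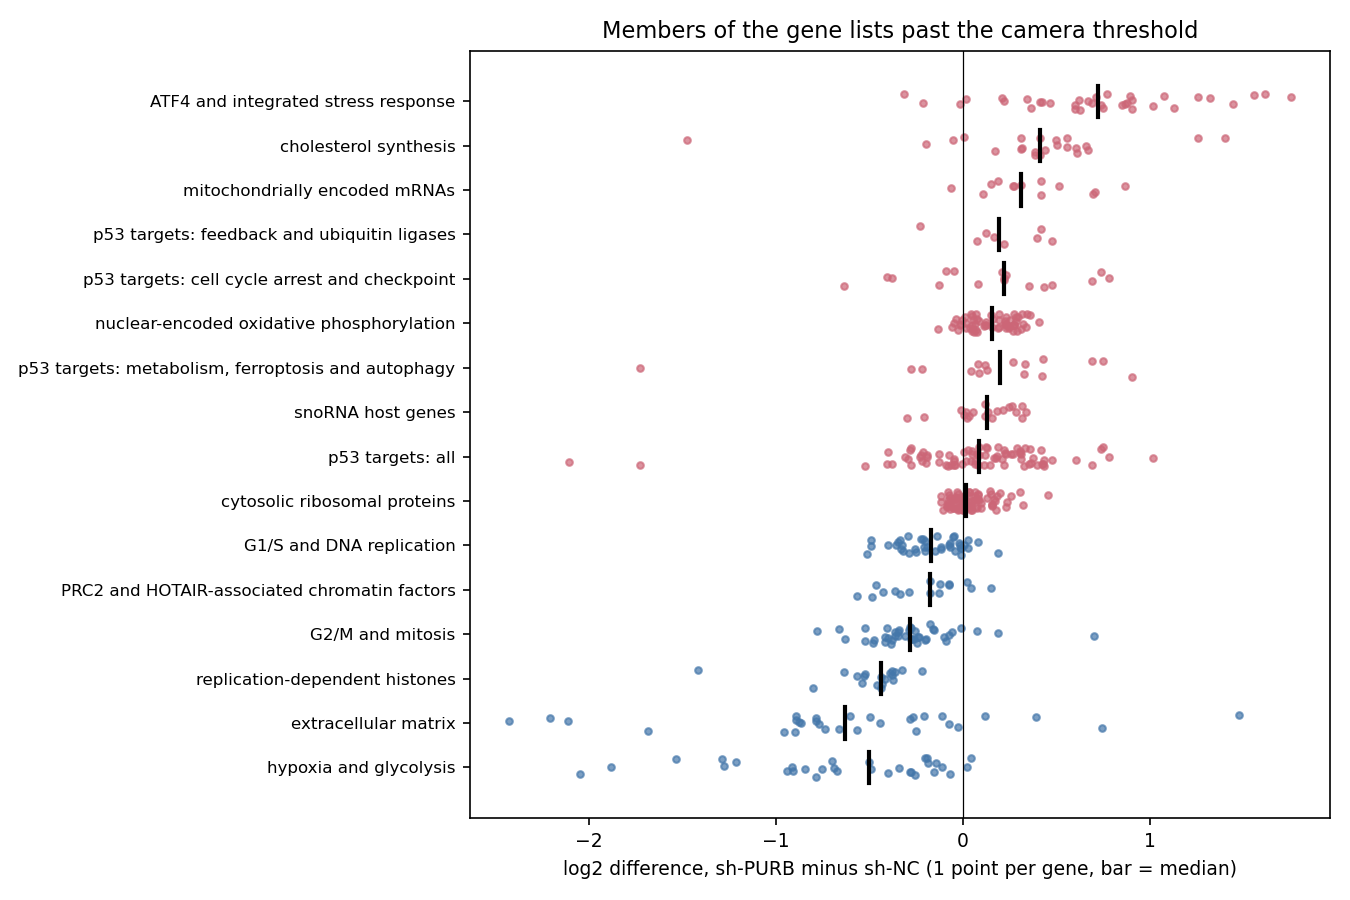
Log2 difference between sh-PURB and sh-NC of each tested member of the 16 gene lists past the camera threshold with the preset correlation. Points are genes, bars are medians, and lists with a median above 0 are red and the others blue. The ATF4 list has a median of 0.72 and the extracellular matrix list one of -0.63 (-0.26 without sh-PURB replicate 1), and no list passed with an estimated correlation.

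The chromatin and PUR lists give mRNA levels of factors linked to HOTAIR and to PURB. The 16 genes of PRC2 (the Polycomb complex that methylates histone H3) and of other chromatin factors associated with HOTAIR had a median of -0.17, with 13 below 0 (median from -0.04 with recomputed TPM to -0.26 without sh-NC replicate 1). MTF2 was at 0.705, PHF1 at 0.722 and HDAC1 at 0.772 of control, and no member was called by limma (5 lower at an unadjusted p under 0.05). The camera adjusted p of 0.0210 (adjusted p = 0.559 with an estimated correlation) rose to 0.0921 without sh-NC replicate 1, 0.073 without sh-NC replicate 2 and 0.0922 without sh-PURB replicate 2, and to between 0.0536 and 0.0993 under 4 other settings. The list of HOTAIR and the HOXC cluster (8 tested) had a median of -0.19 (-0.09 after quantile normalization) and did not pass (camera adjusted p = 0.306), with HOXC9 at 0.720 and HOXC10 at 0.778 of control. The PUR family and partners (9 tested) did not pass (adjusted p = 0.767 by camera), with YBX1 at 1.20 and SP3 at 0.817 times control.

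Markers of other cell types were read as a check for mixed cells. The epithelial markers (7 tested) did not pass (camera adjusted p = 0.956), and their summed 198 to 229 TPM came mostly from KRT8 and KRT18. Blood and immune markers summed to 5.74 to 11.1 TPM. The summed neural markers separated the groups, at 27.6 and 27.1 TPM in sh-NC and 38.7 and 46.1 TPM in sh-PURB, mostly from TUBB3 and NEFL. The blood, neural and HOXD lists had 3, 4 and 3 tested members and were not tested as lists. Across genes, the 2 sh-NC libraries correlated at Pearson r = 0.955, the 2 sh-PURB libraries at 0.961, and libraries of different groups at 0.931 to 0.944. Genes are not independent replicates, so these values only describe the libraries. The first principal component (48.8% of the variance) separated the groups.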

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

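Chosen after seeing the data were the settings with protein-coding genes only, with the length and GC trend removed, with identical rows counted once, and the p53 list without ATF4 list members. The 41 called genes kept their direction in each setting where they were tested. The count of calls by limma was 0 with a pseudocount of 0.1 (2155 genes at an unadjusted p under 0.05), 0 with no filter (3031 of 27206), 0 without the trend (2089) and 0 without any single library (1355 to 2347), a fit with 1 residual degree of freedom whose count does not show dependence on that library. It was 121 with a filter at TPM 5 (31 higher, 90 lower), 80 after median-ratio rescaling (30 and 50), 118 after quantile normalization (45 and 73), 60 with recomputed TPM (26 and 34), 125 with robust moderation (43 and 82), 407 with protein-coding genes only (157 and 250), 66 with the length and GC trend removed (15 and 51) and 23 with identical rows counted once (7 and 16). The cause was not tested, except that the last has fewer rows at the same p. The PURB level kept its direction throughout, with log2 differences from -1.16 to -0.81. It passed only with protein-coding genes (-1.07, adjusted p 0.0314), where other adjusted p-values lay between 0.0714 and 0.457. The replicate numbers are shared by the groups without a stated meaning. Deviations of same-numbered libraries correlated at 0.193 over only 2 pairs, and the second principal component (31.6%) separated the numbers. The block is therefore given only here. With the replicate block 118 genes were called (41 higher, 77 lower), 40 of them among the 41, and ITGA2 moved to an adjusted p of 0.0504. The p53 list stayed past the threshold and 15 other lists passed. The block fit has 1 residual degree of freedom, so its counts do not show how firm the calls are. The p53 list had camera adjusted p-values from 0.0011 to 0.0338, but 0.559 with an estimated correlation. Fry, which tests against no change and not against other genes, gave 0.474 on 2 residual degrees of freedom, where a list could hardly pass. Other lists past the threshold numbered 9 to 17, with 0 by an estimated correlation and 0 by fry, and 9 without sh-PURB replicate 2. Reversals concerned results past no threshold in the fit over all genes. By camera these were the smooth muscle list with TPM 5 (adjusted p 0.999), the unfolded protein response list with recomputed TPM (0.996), and without sh-NC replicate 1 (0.834) or sh-PURB replicate 2 (0.751), and the epithelial list with recomputed TPM (0.996), and without sh-NC replicate 2 (0.306) or sh-PURB replicate 1 (0.573). The p53 DNA repair list reversed without sh-NC replicate 1 (0.911) and without sh-PURB replicate 2 (0.485), and the heat shock list without sh-PURB replicate 1 (0.486). Fry placed the epithelial (0.818), DNA repair (0.939) and heat shock (0.939) lists below 0 where camera placed them above other genes. These are answers to different questions and are not read as reversals: the means of the first pair (-0.05 and -0.01) lie between that of all tested genes (-0.06) and 0. The heat shock mean was 0.01, so there the reference alone does not account for the sign. Over the 4 libraries left out, these adjusted p-values ranged from 0.276 to 0.834 (unfolded protein response), 0.265 to 0.715 (epithelial), 0.234 to 0.911 (DNA repair) and 0.0922 to 0.661 (heat shock). Leaving out a library gave log2 differences of -0.025 to 0.28 for MDM2 (below 0 without sh-NC replicate 1), -0.059 to 0.45 for CLDN4 (below 0 without sh-NC replicate 2) and -0.38 to 0.0051 for DDB2 (above 0 without sh-PURB replicate 1). The cause of these reversals was not tested. Over all lists and settings, 506 comparisons stayed on their side of the threshold, 50 lost and 13 gained a call. For named genes the numbers were 2035, 203 and 90. The list counts include camera at an estimated correlation and fry, where a list could hardly pass. Calls lost there do not show dependence on the processing. With depth unknown, no value has a counting error.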

Other observations

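Chosen only after its result was seen was the test on doxycycline below, as were the protein-coding, identical-row and length and GC settings. The genes named in the next sentence and the one after were also picked after the data were seen, as those with the smallest p-values in each direction, among protein-coding genes fitted alone, that are named nowhere else. Higher in sh-PURB were MAP3K8, a MAP kinase kinase kinase (3.83 ± 0.262 to 30.3 ± 10.6 TPM), SREBF1, which encodes the lipogenic transcription factor SREBP1 (11.1 ± 0.611 to 52.5 ± 20.4 TPM), the lysyl oxidase homolog LOXL4 at 3.63 times control, NTM at 3.49 times, SPX at 3.94 times and FKBP9 at 1.96 times. Lower were the protease inhibitor A2M (22.6 ± 9.21 to 1.66 ± 0.406 TPM), ID1, an inhibitor of basic helix-loop-helix factors (188 ± 32.6 to 53.2 ± 12.8 TPM), GUCY1A1 (4.16 ± 1.19 to 0.192 ± 0.0152 TPM), CCKAR, MMD and ITPRID2. Their limma adjusted p-values among protein-coding genes lay between 0.0020 and 0.00527.

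Several lists missed the camera threshold while single members differed. NF-kB and inflammatory genes (15 tested, camera adjusted p = 0.0549, 0.00182 without sh-PURB replicate 1, 0.0164 without sh-NC replicate 2, 0.0463 after quantile normalization, 0.0286 with recomputed TPM and 0.0359 among protein-coding genes) had 3 members lower when adjusted over the list alone, the inhibitor NFKBIA at 0.446 of control, IER3 at 0.466 and the chemokine CXCL8 at 0.289. Among immediate early genes (19 tested, adjusted p = 0.217 by camera, 0.0333 without sh-NC replicate 1 and 0.030 with no filter), JUNB at 0.413 and IER3 were lower and MYC, at 2.00 times control, was higher when adjusted over the list alone. Among targets of NRF2 (19 tested, camera adjusted p = 0.221), NQO1 at 0.612 of control, AKR1C3 at 0.461 of control and the ferritin chains FTH1 and FTL (both 1.43-fold lower) were lower and SLC7A11 was higher in the same count. The unfolded protein response list (22 tested, adjusted p = 0.693 by camera, mean -0.06, median 0.03, from -0.05 to 0.18 over settings) held 4 lower chaperone and folding genes, PDIA6, CRELD2, HSP90B1 and PDIA4, at 0.686 to 0.743 of control. NPC2, a lysosomal cholesterol carrier, was called lower over all genes (220 ± 17.3 to 91.7 ± 3.46 TPM) in a lysosome list that did not pass (29 tested, camera adjusted p = 0.494). The interferon list (24 tested, adjusted p = 0.145), the smooth muscle list (17 tested, 0.164), the osteoblast list (8 tested, 0.121), the heat shock list (14 tested, 0.548) and the list of abundant structured RNAs (19 tested, 0.130) did not pass camera. The interferon list passed, lower, with the filter at TPM 5 (0.0446). The structured RNA list passed, lower, without sh-NC replicate 1 (0.00693), with recomputed TPM (0.00307), after quantile normalization (0.0392) and with the length and GC trend removed (0.0257). In the smooth muscle list TNNT2 went from 0.184 ± 0.116 to 2.53 ± 0.494 TPM.

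The ATF4 and integrated stress response list was higher, with 33 of 36 members above 0. Removing a trend with transcript length and GC content left its camera adjusted p at 1.63e-21, so that trend is not the whole cause. Recomputing TPM without the most abundant RNAs left the adjusted p at 2.69e-16. Camera compares the list with all other genes, and the recomputation moves all genes nearly alike, so this call could hardly be lost. The move itself, from -0.06 to 0.08 in the median of all genes, was small beside the list's median of 0.72. The camera call of this list is lost with an inter-gene correlation estimated from these libraries (adjusted p = 0.559). That fit has 2 residual degrees of freedom and could hardly be passed, so the loss does not show that correlation between members makes the call. Doxycycline was given to the sh-PURB libraries only, with 0 sh-NC libraries given doxycycline, and a direct effect of the drug on this list cannot be told apart from one of the knockdown. Doxycycline inhibits mitochondrial translation, so a candidate explanation is a response to the drug, and PURB loss stays open as well. An effect of the hairpin other than PURB loss cannot be told apart from these either. The same holds for every other difference between these groups.

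U1 small nuclear RNA was lower (RNU1-1 at 0.425 of control). Among tested rows named as spliceosomal small nuclear RNAs or their pseudogenes, with identical rows counted once, the difference was mixed. Of 214 such rows 126 were lower, 49 of them without overlap between groups, and 88 were higher, 32 of them without overlap, where chance gives 35.7 in each direction. Both are smaller shares than over all 14269 tested genes, of which 4185 were lower and 2648 higher without overlap. Of the 32 rows with a mean of at least 10 TPM, 28 were lower, 18 without overlap, and 4 were higher, 2 without overlap. Here chance gives 5.33 without overlap in each direction. RNU4-1 was at 0.301 of control, while RMRP and RPPH1 differed by -0.11 and -0.04 on the log2 scale. Loss of shorter fragments would make the difference rise with RNA length. Over 163 short structured RNAs Spearman's rho was -0.258 (Pearson r = -0.168, two-sided permutation p = 0.00088, across genes, which are not independent replicates). That set pools RNAs of low and high level. Among abundant ones, RNU5B-1 (116 nt), RNU4-1 (141 nt) and RNU1-1 (164 nt) differed by -1.99, -1.72 and -1.24, and the longer RMRP (264 nt) and RPPH1 (333 nt) by little. Others broke this order, such as SCARNA21 (139 nt) at -0.14 and RNU6-1 (107 nt) at -0.26. The falls were uneven, with the rows U2 and RNU2-2P at -0.39 and -0.96. RNU5B-1, SCARNA21, RNU6-1, U2 and RNU2-2P were named after seeing their values. Abundant RNAs were not tested apart, so loss of shorter fragments is not excluded for them. Moving of reads between copies would leave the sum over U1 rows alike, but it fell by 1.22 on the log2 scale, from 42564 and 46949 TPM to 17697 and 20767 TPM over 145 rows. A hypothesis is that levels of U1 and other abundant small nuclear RNAs differ between these cells, and a difference in RNA extraction or in how total RNA was recovered was not tested.

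The p53 target list was placed higher by camera with a small median difference. Without the 2 members shared with the ATF4 list, GDF15 and SESN2, its adjusted p was 0.00542, and with the length and GC trend removed it was 0.00155, so neither is the whole cause. The p53 sub-lists were not retested without members shared with the ATF4 list. The call of the full list is lost with an estimated correlation (0.559, again on 2 residual degrees of freedom), the members go both ways, and doxycycline stays open here too.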
